A study of Rattus norvegicus with 6 samples.

How the data were processed

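The series holds 6 samples of rat renal cortex, 3 from rats given corn oil and 3 from rats given DNPT, which the labels describe as separate animals and as biological replicates. Per the labels, total RNA was prepared with a kit, amplified to cRNA, labelled with Cy3 and hybridised to Agilent arrays. Per the submitters' processing notes, Agilent Feature Extraction 10.7 read the scans. The deposited scanner files hold, per the file headers, an intensity per spot on a linear scale, the processed signal, made by Feature Extraction with correction for background. The deposited value table holds a linear ratio: each array's values equalled its processed signal divided by a constant close to its 75th percentile (100% of probes within 0.5% of a single factor), with no centring, and column medians ran from 0.112 to 0.116. The step that made the table is not given in the sources used here, and its direction was settled by this match.

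Control spots and 113 values flagged as non-uniform or population outliers were left out, while saturated spots were kept. Log2 of the processed signal minus the 75th percentile of each array was the measure. A probe was tested if it was well above background on at least 3 of the 6 arrays with at least 2 values per group. Probe accessions were matched without versions to a RefSeq gene table of assembly GRCr8, used for names only. Of 61537 probes, 28206 matched 1 gene, 0 matched several and 33331 matched none, and the matched ones covered 15645 genes. No coordinates are given, because the array design uses an older assembly. Of 44305 probes that passed the filter, a gene was represented by the tested probe with the highest mean signal, and unnamed probes were tested on their own, which left 34915 features.

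Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without covariates, with Benjamini-Hochberg adjustment over all features at 0.05. Gene lists were compared with camera at a preset correlation of 0.01, for lists with at least 5 tested members, adjusted over the 39 lists tested. There were 40 lists, for kidney cell types, neighbouring tissue and pathways, and they, the groups, the tests, the named genes and most alternatives were fixed before the data were examined. The named genes were to be the 12 largest changes per direction that passed without overlap, or, where none passed, the 5 with the smallest p as values; per list up to 4 members that passed, or else its 2 brightest; and Havcr1, Lcn2, Clu, Spp1, Cdkn1a, Hmox1, Nqo1 and Cyp1a1. Some items that fall under the rule are not reported here. Other genes named in the text were chosen after their values were seen, among them list members that passed over their list alone. Each list's median was set among 10000 random lists drawn from 20 bins of mean signal. Their genes were drawn singly, so the random lists lack the shared variation of a real list. Nor does a percentile among them measure the spread between rats. Lists without a call also reached extreme percentiles, such as CAR and PXR targets at 99.8. The 3 against 3 design has 10 splits, and an exact permutation test of a single value cannot go below 0.1.

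Alternatives were quantile normalization, normexp background correction with an offset of 50 followed by quantile normalization, median scaling, the value table, other filters and probe rules, an intensity trend, array weights, a minimum log2 change of 1, slide or replicate number as a block, slide 1 alone, each sample left out, an estimated correlation and fry. The plan named the mean signal for normexp; the median signal of each spot was used in its place. Cyclic loess, a robust prior with a trend, adjustment over list genes only and the counts of clock genes under each alternative were added after seeing the data. The procedure was tested on simulated data: over 5 simulations of the DNPT and vehicle comparison with 34915 features, 200 of them changed, 42% were called at a log2 change of 1 and 79.6% at 2, with a mean of 7.6 false calls, and a list shifted by 0.5 was called in all 5. The simulated noise was independent between genes, while estimated correlations in the called lists reached 0.34 (erythroid and blood). The shift of 0.5 was also larger than the median change of any called list, at most 0.43 in size. The simulation therefore does not show how the set test behaves on the real lists. Members of the shifted list were changed besides the 200 features. Each gene's observed SD was taken as its true SD, and no effect of slide was simulated. The shares called thus do not give the power of the gene test on the real data. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.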

Results

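Messenger RNA levels were measured in the renal cortex of 6 male Sprague-Dawley rats, 5 weeks old when purchased. The 3 rats of the DNPT group were given N,N'-dinitrosopentamethylenetetramine, an N-nitroso compound, at 200 mg/kg/day for 4 weeks, and the 3 rats of the vehicle group were given corn oil for the same time. Each kidney sample was hybridised to a 1-colour Agilent array with 61537 probes that were not controls. Between 42116 probes (DNPT replicate 3) and 45167 probes (vehicle replicate 2) were well above background on an array, and the number of arrays limits the precision of every value given here. The 3 vehicle samples and DNPT replicate 1 shared slide 1 and scan day 1, and DNPT replicates 2 and 3 were on slide 2 and scan day 2. Signals are log2 values relative to the 75th percentile of their array, with means ± SD over n = 3 rats, and changes are DNPT minus vehicle with their standard error (SE).

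The comparison of the groups addresses which transcripts of the renal cortex differ after DNPT dosing. Genes of the circadian clock had the largest mean absolute change of the 39 lists tested (1.55). Dbp, a clock-controlled transcription factor, had a signal of 6.14 ± 0.45 in DNPT rats and 3.28 ± 0.04 in vehicle rats, and Bmal1, the central activator of the clock, was at -1.18 ± 0.94 against 1.67 ± 0.10. Lists of T, B and NK lymphocyte and macrophage genes lay lower in DNPT rats. The 9 lists called higher included oxidative phosphorylation, intercalated cells, distal tubule, red blood cells and the cell cycle. Oxidative phosphorylation had the smallest p of the set test, but its median lay at percentile 31.3 of matched random lists. The cell cycle median was -0.03 in DNPT replicate 3, and the call was lost without DNPT replicate 2 or vehicle replicate 1. The distal tubule call was lost with slide as a block. The set test behind these calls used a preset correlation. It called no list when the correlation was estimated, a setting that also leaves the test far fewer degrees of freedom. Genes of the DNA damage response and of tubular injury did not shift as lists. Across all 34915 features tested, of which 12687 were named genes, limma with Benjamini-Hochberg adjustment called 0 genes higher and 0 lower at an adjusted p under 0.05. An unadjusted p under 0.05 was reached by 4227 features, 2076 higher and 2151 lower, where chance gives 1746. That number was 2393 with slide as a block, 2696 on slide 1 alone, 2463 without vehicle replicate 1, 2436 without vehicle replicate 2 and 7275 without DNPT replicate 1. All 3 DNPT values lay above all 3 vehicle values in 4157 features and below them in 2906, together 20.2% of those tested, where chance gives 10%.

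No gene passed in either direction, so the 5 named genes with the smallest p in each direction are given as values. On the higher side, the Dbp change was 2.86 (SE 0.23, adjusted p = 0.112). Slc39a4, a zinc importer, had a change of 0.87 (SE 0.09, adjusted p = 0.149), Nme4, a mitochondrial nucleoside diphosphate kinase, 0.68 (SE 0.07, adjusted p = 0.163), and Ccnb2, a mitotic cyclin, 1.01 (SE 0.12, adjusted p = 0.173). Ccdc116 was not well above background in any vehicle sample and was at least 2.13-fold brighter in DNPT rats (adjusted p = 0.112). On the lower side, Ppard, a nuclear receptor for fatty acids, had a change of -1.75 (SE 0.17, adjusted p = 0.149). Timd2, a ferritin receptor, was at 1.26 ± 0.05 in DNPT rats and 2.15 ± 0.08 in vehicle rats, and Ugt1a1, the enzyme that conjugates bilirubin, was at 0.71 ± 0.08 and 1.51 ± 0.04, both with an adjusted p of 0.149. Uts2b and Glt6d1 were not well above background in any DNPT sample and were at least 1.21-fold and 1.39-fold brighter in vehicle rats (adjusted p = 0.112 and 0.149). In all 10 genes the 3 DNPT values lay on the same side of all 3 vehicle values. Their choice by smallest p in the same comparison makes that likely, so it adds no support. The bounds set the bright group's mean against the higher of each array's lowest signal well above background and the probe's own signal.

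Of the 15 clock genes tested, 6 rose and 5 fell when p-values were adjusted over the list alone, and 0 passed over all genes tested. Adjustment within each list does not allow for the number of lists. Adjusted over the 733 list genes together, only Dbp, Nfil3, Slc39a4 and Ccnb2 passed. Other genes given here and below as rising or falling over their list alone did not pass in that way. Among the genes that rose, Dbp was 7.28-fold higher and Nr1d1, a repressor of Bmal1 transcription, was 5.96-fold higher (0.15 ± 0.41 against -2.43 ± 0.63, limma p adjusted over the list alone 0.00176). Its paralogue Nr1d2 had a change of 1.53 (SE 0.22), Tef, a relative of Dbp, 1.24 (SE 0.21), and Per2, a repressor of the clock, 0.97 (SE 0.22). Ciart, another repressor, was not well above background in any vehicle rat and was at least 7.04-fold higher in DNPT rats. Among the genes that fell, Bmal1 was 7.23-fold lower (limma p adjusted over the list alone 0.00207), its partner Npas2 4.24-fold lower and Nfil3, a repressor that opposes Dbp, 3.82-fold lower. Cry1 fell by 1.11 (SE 0.21) and Per1 by 0.57 (SE 0.19). Clock (-0.13, SE 0.10), Cry2 (0.25, SE 0.30) and Usp2 (0.41, SE 0.21) did not pass. The brightest Per3 probe had a change of 0.02, while the other 4 Per3 probes on the array had changes of 1.01 to 2.30, so the probes of that gene disagree. Npas2 probes ranged from -2.28 to -0.33.

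The clock differences were also present in the only DNPT rat of slide 1. DNPT replicate 1 differed from the vehicle mean by 2.89 for Dbp, 2.40 for Nr1d1, -3.01 for Bmal1 and -1.91 for Nfil3, and 5 clock genes rose and 5 fell with slide as a fixed block. Slide 2 holds no vehicle sample, so every value with slide as a block, here and for the lists, sets DNPT replicate 1 alone against the 3 vehicle rats and assumes that it varies like the other samples. With each sample left out in turn, 5 or 6 rose and 4 or 5 fell. The labels used here give no time of day at which kidneys were taken. Because the members moved both ways, camera did not call the list as shifted (median change 0.25, adjusted p = 0.423). fry, which also tests for change in either direction, gave an adjusted p of 0.00695 for the list and called 16 of the 39 lists in this way. Smaller adjusted p-values came from metallothioneins and zinc transport (0.000432), inner medulla (0.00138), distal tubule (0.00302) and lymphocytes (0.00609). The mean absolute change over the 15 genes, 1.55, was larger than in each of 10000 random lists matched on mean signal.

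**Figure D1:**
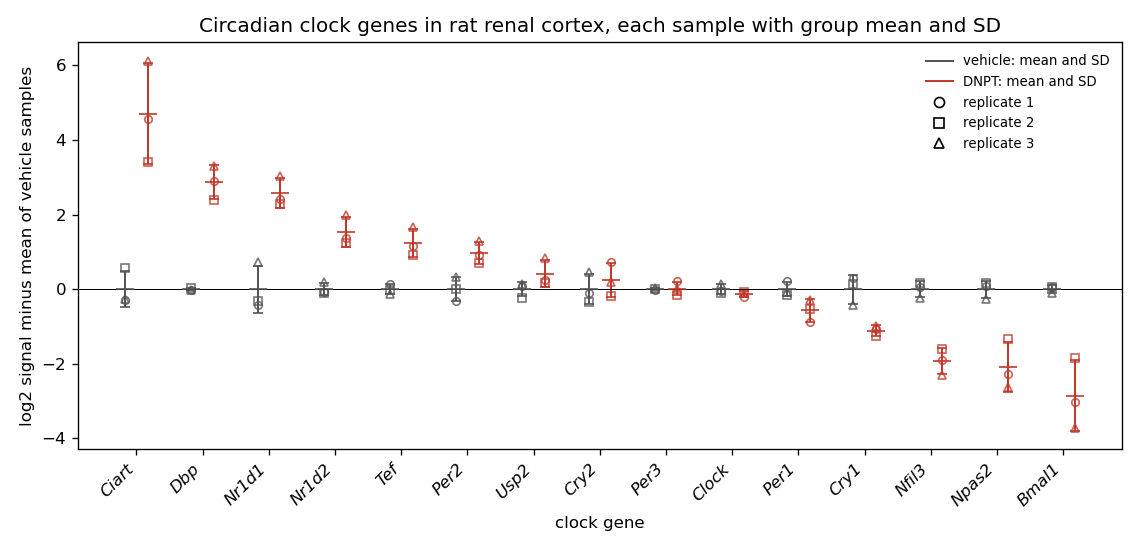
Log2 signal of the 15 clock genes tested, each relative to the mean of the vehicle samples (vertical axis, log2), with 1 open symbol per rat and a bar with whiskers for the mean and SD of each group of 3. The DNPT values of Ciart, Dbp, Nr1d1, Nr1d2, Tef and Per2 lie above, and those of Per1, Cry1, Nfil3, Npas2 and Bmal1 below, all vehicle values of the same gene; the Ciart vehicle values are not well above background.

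Among lists for segments of the nephron, camera with a preset correlation of 0.01 called intercalated cells, the distal convoluted and connecting tubule and the proximal tubule higher in DNPT rats. All 13 intercalated cell genes had positive changes (median 0.27, adjusted p = 0.00344; adjusted p = 0.60 with an estimated correlation), with the proton pump subunit Atp6v1g3 at 0.49 (SE 0.16) and the anion exchanger Slc26a4 at 0.36 (SE 0.13). The list's median lay at percentile 99.99 of random lists matched on mean signal, and in DNPT replicate 1, the only DNPT rat of slide 1, it was 0.35 (adjusted p = 0.00796 with slide as a block). Of 10 distal convoluted and connecting tubule genes, 8 had positive changes (median 0.18, adjusted p = 0.0160; adjusted p = 0.60 with an estimated correlation), among them Klk1, a kallikrein, at 0.16 (SE 0.16), while the sodium chloride cotransporter Slc12a3 was at -0.11 (SE 0.16). The call was lost with slide as a block (median 0.17, adjusted p = 0.0718). Of 37 proximal tubule genes, 23 had positive changes (median 0.12, adjusted p = 0.0377; adjusted p = 0.67 with an estimated correlation). That median lay at percentile 54.9 of matched random lists, and the call was lost with slide as a block, where the median was 0.10 (adjusted p = 0.703). It was also lost, with larger medians, without vehicle replicate 2 (median 0.15, adjusted p = 0.0961) and DNPT replicate 3 (0.17, 0.0507), and, with smaller medians, without vehicle replicate 3 (0.08, 0.140) and DNPT replicate 2 (0.045, 0.192). Miox was at 0.08 (SE 0.15) and the gluconeogenic enzyme Fbp1 at 0.26 (SE 0.10). The vitamin D and phosphate list, which shares 3 genes (Calb1, S100g and Trpv5) with the distal list and 3 with the proximal list, had 10 of 14 positive changes (median 0.15, adjusted p = 0.0328; adjusted p = 0.60 with an estimated correlation; 0.0718 with slide as a block, where the median was 0.17), and its call was lost, with medians of 0.13 to 0.18, without vehicle replicate 3 (adjusted p = 0.0681) and without DNPT replicate 1 (0.0646) or 3 (0.0507). Its brightest members were the phosphate transporters Slc34a1 (0.09, SE 0.15) and Slc34a3 (0.27, SE 0.09). No member of these 4 lists passed, either over all genes or adjusted over the list alone.

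The remaining cell types of the kidney gave no call. Collecting duct principal cell genes had a median change of 0.19 (adjusted p = 0.0823), with Aqp2, the water channel, at -0.34 (SE 0.16) and Hsd11b2 at 0.49 (SE 0.16). Endothelial genes had a median of 0.11 (adjusted p = 0.0513), with Plvap at 0.11 (SE 0.10) and Kdr at 0.25 (SE 0.12). Medians were -0.07 for the thick ascending limb (adjusted p = 0.680), -0.11 for podocytes (adjusted p = 0.423), 0.08 for mesangial, smooth muscle and pericyte genes (adjusted p = 0.481), -0.01 for fibroblast and matrix genes (adjusted p = 0.904) and -0.10 for inner medulla, osmolyte and urothelium genes (adjusted p = 0.716). Umod, made by the thick ascending limb, was at 7.98 ± 0.24 in DNPT and 8.16 ± 0.15 in vehicle rats, and the podocyte gene Podxl at 4.34 ± 0.34 and 4.02 ± 0.14. Lists for tissue next to the kidney did not differ either. Perirenal fat had a median of -0.13 (adjusted p = 0.680), and adrenal genes had a median of -0.31 but a mean of 0.03 (adjusted p = 0.680).

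Lymphocyte genes lay lower in DNPT rats. Of 18 T, B and NK cell genes, 16 had negative changes (median -0.43, adjusted p = 0.000173; adjusted p = 0.60 with an estimated correlation), and the list's median was below that of each of 10000 matched random lists. Adjusted over the list alone, Cd2, a T cell surface protein, fell and Cd79b, part of the B cell receptor, rose (1.14, SE 0.20, with no value for DNPT replicate 2). Neither passed over the genes of all lists together. Cd2 was not well above background in any DNPT rat and was at least 1.35-fold brighter in vehicle rats. Among the brightest members, Cd3d was at -0.36 ± 0.16 in DNPT and -0.01 ± 0.06 in vehicle rats, and the chemokine Ccl5 had a change of -0.15 (SE 0.14). The median was -0.51 in DNPT replicate 1, -0.30 in replicate 2 and -0.50 in replicate 3, and with slide as a block, which rests on replicate 1 alone, the adjusted p was 4.3e-05. Of 20 macrophage and dendritic cell genes, 15 had negative changes (median -0.17, adjusted p = 0.0434; adjusted p = 0.71 with an estimated correlation). Adjusted over the list alone, the inhibitory Fc receptor Fcgr2b fell by 0.62 (SE 0.10) and Cd74, the invariant chain of MHC class II, rose by 0.60 (SE 0.13), while Lyz2 was at -0.26 (SE 0.15). Fcgr2b and Cd74 did not pass over the genes of all lists together. The median of this list was -0.39 in DNPT replicate 1, -0.02 in replicate 2 and -0.19 in replicate 3. The call was lost, with medians of -0.19 to -0.09, without vehicle replicate 1 (adjusted p = 0.17) or 2 (0.0961) and without DNPT replicate 1 (0.568) or 3 (0.0507). Interferon response genes had a median of -0.06 (adjusted p = 0.423), but medians of -0.43 in DNPT replicate 1 and 0.17 in replicate 2, so that the list was called lower with slide as a block (adjusted p = 1.36e-05) and without DNPT replicate 2 (0.00410). Complement (median 0.03, adjusted p = 0.904) and inflammatory cytokine and NF-kB target genes (median -0.09, adjusted p = 0.481) did not differ.

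Red blood cell genes lay higher. Of 9 erythroid and blood genes, 7 had positive changes (median 0.32, adjusted p = 0.0116; adjusted p = 0.60 with an estimated correlation; 0.0252 with slide as a block). Adjusted over the list alone, 3 rose. They were Hemgn, a nuclear protein of red cell precursors (1.28, SE 0.29), Ahsp, the chaperone of alpha globin (0.84, SE 0.22), and Hbb-b1 (0.36, SE 0.10). None of them passed over the genes of all lists together. Hba-a1 was at 8.54 ± 0.08 in DNPT and 8.20 ± 0.18 in vehicle rats. Iron and heme genes had 19 of 22 positive changes (median 0.19, adjusted p = 0.0282; adjusted p = 0.71 with an estimated correlation), but a median of 0.03 within slide 1 (adjusted p = 0.861 with slide as a block). The call was lost without vehicle replicate 1 (median 0.22, adjusted p = 0.0702) or 3 (0.23, 0.0712) and without DNPT replicate 3 (0.05, 0.446). This list holds Hp and Hpx, which varied between samples with Alb and other liver transcripts, highest in DNPT replicate 3. Cell cycle genes had 28 of 35 positive changes (median 0.23, adjusted p = 0.0125; adjusted p = 0.71 with an estimated correlation). Their median was 0.21 in DNPT replicate 1, 0.59 in replicate 2 and -0.03 in replicate 3, and the call was lost without DNPT replicate 2 (median 0.04, adjusted p = 0.130), without vehicle replicate 1 (0.12, 0.129) and with slide as a block (0.21, 0.0888). On slide 1 alone, which also rests on DNPT replicate 1, the list was called higher (median 0.26, adjusted p = 0.000899). Ccnb2 was the only member to rise when adjusted over the list alone, while the brightest members Kif11 (0.12, SE 0.10) and Pcna (-0.04, SE 0.11) lay near 0.

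Lists chosen for responses to a nitroso compound gave 1 call. Alkylation and base excision repair genes had 18 of 21 positive changes (median 0.12, adjusted p = 0.0230; adjusted p = 0.60 with an estimated correlation). Within slide 1 their median was 0.05, and the call was lost with slide as a block (adjusted p = 0.605), without vehicle replicate 3 (0.0850) and without DNPT replicate 3 (0.111). Apex1 was at 0.12 (SE 0.09) and Parp1 at 0.14 (SE 0.24). The DNA damage response list had 13 positive and 12 negative changes (median 0.01, set test directed lower, adjusted p = 0.765). Cdkn1a, the cell cycle inhibitor p21, was at 4.98 ± 0.22 in DNPT and 5.35 ± 0.03 in vehicle rats. Formaldehyde detoxification and one-carbon genes had a median of 0.10 (adjusted p = 0.196), with Aldh7a1 at 0.25 (SE 0.07) and Aldh1a1 at 0.13 (SE 0.08). The Nrf2 list had 28 of 36 positive changes (median 0.16, mean 0.05, adjusted p = 0.0513), and was called higher in 8 of 22 alternatives, among them without vehicle replicate 3 (0.00781) and without DNPT replicate 3 (0.00326). Nqo1, a quinone reductase, was at -2.18 ± 0.27 against -3.03 ± 0.26 (adjusted p = 0.334 over all genes), Hmox1 at 0.10 (SE 0.35), Ftl1 at 0.27 (SE 0.13) and Fth1 at 0.20 (SE 0.11). Other members had negative changes that did not pass, among them Gclm (-1.84, SE 0.61), Akr1b8 (-1.48, SE 0.93) and Gclc (-0.71, SE 0.62), and Slc7a11, not well above background in any DNPT rat, was at least 1.29-fold brighter in vehicle rats. The aryl hydrocarbon receptor list had 4 tested members and no set test. Adjusted over the list alone, Nqo1 rose and Ugt1a6 fell by 0.31 (SE 0.10), but neither passed when adjusted over the larger Nrf2 list, which also holds them (adjusted p = 0.114 and 0.143). Cyp1a1, the best known target of that receptor, was not tested, since its probe was well above background on 1 of the 6 arrays. CAR and PXR targets had a median of 0.29 (adjusted p = 0.389), with Alas1 at 0.30 (SE 0.13) and Por at 0.40 (SE 0.13).

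Markers of kidney injury did not shift as a group. The tubular injury and dedifferentiation list had 15 positive and 16 negative changes (median -0.01, mean 0.01, set test directed lower, adjusted p = 0.887). Its member Fgg varied between samples with the liver transcripts. Havcr1, which encodes kidney injury molecule 1, was at -4.64 ± 0.43 in DNPT and -4.30 ± 0.29 in vehicle rats. Lcn2 was at -2.16 ± 0.28 and -1.72 ± 0.16, Clu at 3.88 ± 0.57 and 3.87 ± 0.08, and Spp1 at 2.56 ± 0.13 and 2.66 ± 0.40. The brightest member, Tff3, spread widely within both groups (3.69 ± 1.37 and 4.25 ± 1.29).

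Of the metabolic lists, oxidative phosphorylation was called. All but 2 of its 40 genes had positive changes (median 0.13, adjusted p = 2.22e-05; adjusted p = 0.60 with an estimated correlation), with Atp5f1a at 0.17 (SE 0.11) and Cox6a1 at 0.19 (SE 0.09). The median lay at percentile 31.3 of random lists matched on mean signal, and the call was lost after quantile normalization, normexp and cyclic loess. The proximal tubule, vitamin D and phosphate, and iron and heme calls were also lost after quantile normalization and after cyclic loess. The alkylation repair call was lost after normexp and cyclic loess. With normexp the vitamin D and phosphate and the proximal tubule lists were not called either. Medians were 0.10 for amino acid catabolism (adjusted p = 0.0599), 0.13 for PPAR alpha and fatty acid oxidation (adjusted p = 0.153), 0.14 for cholesterol synthesis (adjusted p = 0.153) and -0.05 for fatty acid and triglyceride synthesis (adjusted p = 0.423). Glycolysis had a median of 0.02 but a mean of -0.01 (adjusted p = 0.741). Of the stress lists, metallothioneins and zinc transport had a median of 0.09 (adjusted p = 0.196). Slc39a4 rose when adjusted over the list alone, and the bright metallothioneins Mt1 (0.09, SE 0.10) and Mt2A (0.16, SE 0.11) lay near 0, while Mt3 had a change of 1.59 (SE 0.67) that did not pass. Among ER stress and ATF4 targets (median -0.04, adjusted p = 0.321), Ddit4, an inhibitor of mTORC1, fell by 0.60 (SE 0.11) when adjusted over the list alone. Among hypoxia genes (median 0.06, adjusted p = 0.873), Ankrd37 rose (0.65, SE 0.17), while Car9 fell by 0.41 (SE 0.10) and Pfkfb3 by 0.55 (SE 0.11), adjusted over the list alone. Ddit4, Ankrd37, Car9 and Pfkfb3 did not pass over the genes of all lists together. The Pfkfb3 probes disagreed in sign, from -0.55 to 0.21. Heat shock genes had a median of 0.02 and a mean of -0.02 (adjusted p = 0.753).

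**Figure D2:**
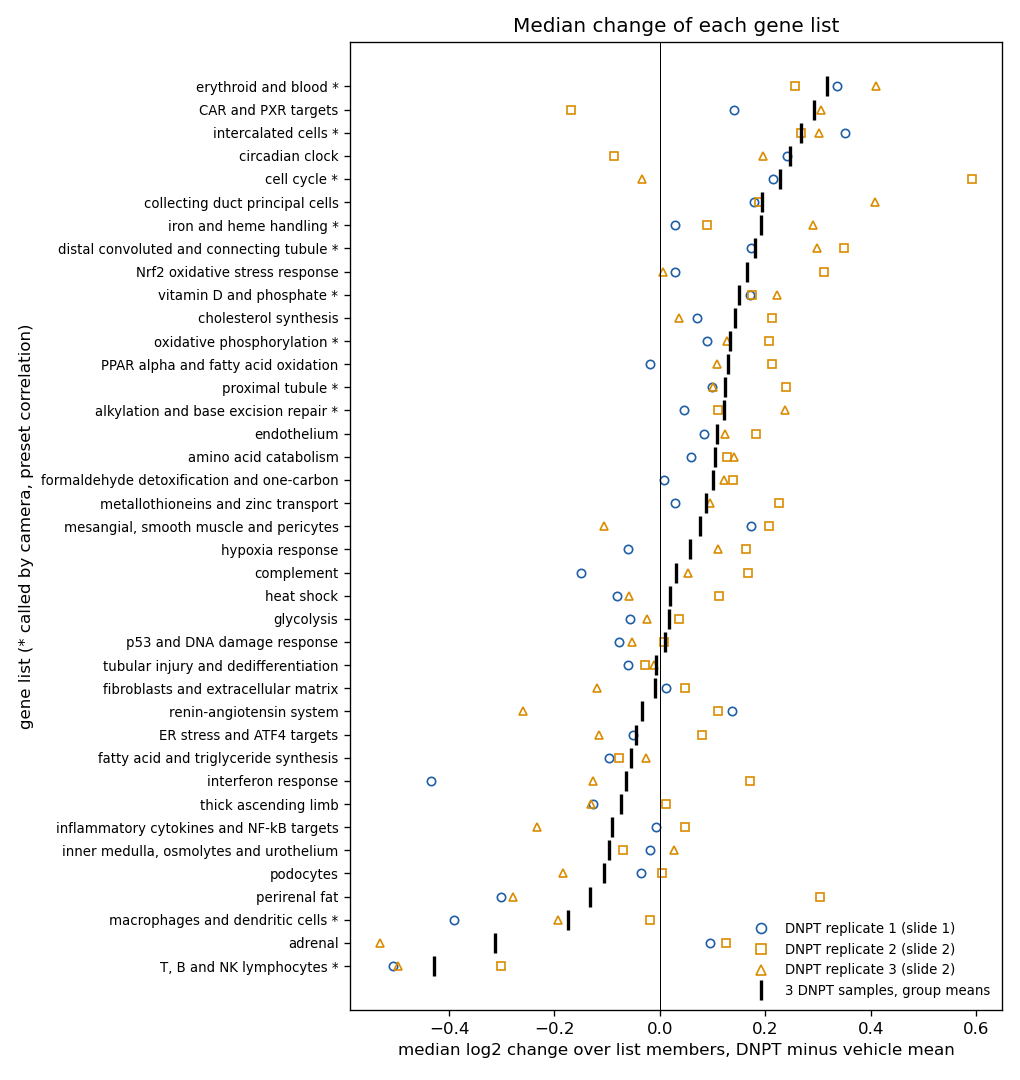
Median log2 change of each of the 39 lists tested (horizontal axis, DNPT minus the vehicle mean), with open symbols for each DNPT rat, coloured by slide, and a black bar for the median over changes of group means; an asterisk marks lists called by camera with the preset correlation. T, B and NK lymphocyte genes lie between -0.51 and -0.30 in the 3 rats, while the cell cycle list ranges from -0.03 to 0.59.

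In all, camera called 9 lists higher and 2 lower of the 39 tested, 0 with an estimated correlation, and fry, which does not set a list against other genes, called 3 higher and 0 lower (distal tubule, vitamin D and phosphate, and metallothioneins, adjusted p = 0.0452). For the distal tubule and the vitamin D and phosphate lists the estimated correlations were -0.026 and -0.064, below the preset 0.01. A larger correlation thus does not account for the loss of those camera calls. The lymphocyte list, with an estimated correlation of 0.056, had the same adjusted p of 0.60 in that setting. With an estimated correlation camera tests on the 4 residual degrees of freedom of the fit, far fewer than with a preset correlation. The loss of a call there is therefore no measure of the correlation within a list. Bright genes lay slightly higher on slide 2. Among features with a mean log2 signal above 6, the median difference from the vehicle mean was 0.06 in DNPT replicate 1, 0.19 in replicate 2 and 0.16 in replicate 3, and among those below -4 it was -0.04, -0.06 and -0.16. Calls of single genes depended on individual samples: 37 genes were higher and 603 lower without DNPT replicate 1, the only DNPT sample on slide 1, and 3 higher and 0 lower without vehicle replicate 2.

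**Figure D3:**
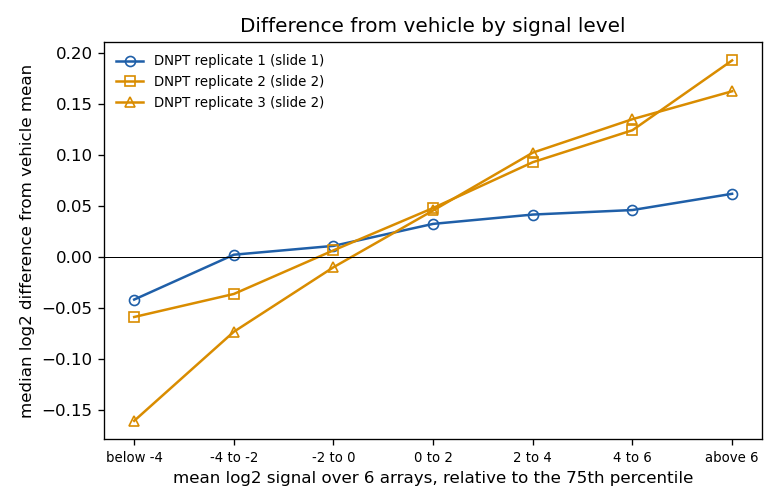
Median log2 difference of each DNPT rat from the vehicle mean (vertical axis) for tested features grouped by mean log2 signal over the 6 arrays relative to the 75th percentile (horizontal axis). In the brightest group the medians are 0.06 for DNPT replicate 1 on slide 1 and 0.19 and 0.16 for replicates 2 and 3 on slide 2.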

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

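Cyclic loess, the robust prior, adjustment over the list genes alone and the clock counts were chosen after seeing the data. The main counts were 0 genes higher, 0 lower, 9 lists higher and 2 lower. Genes higher numbered 4 with normexp (Dbp and 3 unnamed probes), 1 with slide as a fixed block, 1 on slide 1 alone (Fam111a, named after its values were seen), 1 with a trend and robust prior, and 3 adjusted over the 733 list genes only (Dbp, Slc39a4 and Ccnb2). Genes lower numbered 1 with normexp (Timd2) and 1 over the list genes only (Nfil3). Under the other alternatives that leave out no sample, both counts were 0. Leaving out 1 sample gave 0 to 37 genes higher and 0 to 603 lower. Both upper values were without DNPT replicate 1, and 3 genes were higher without vehicle replicate 2 (Crygd, Cryga and an unnamed probe, chosen after their values were seen). Apart from the calls without DNPT replicate 1, the cause was not tested.

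Lists called higher numbered 5 with quantile normalization, 5 with normexp, 4 with cyclic loess, 1 without a filter on dim probes, 3 with slide as a block, 4 on slide 1 alone, 0 with an estimated correlation and 3 with fry, but 11 with median scaling, 11 with array weights, 12 with an intensity trend and 12 with a trend and robust prior. Lists called lower numbered 3 with normexp, 3 with slide as a block, 3 on slide 1 alone, 1 without the filter, 1 with array weights, 0 with an estimated correlation and 0 with fry. Leaving out 1 sample gave 6 to 9 lists higher and 1 to 3 lower. The Nrf2 list, not called with the main choices, was called higher with median scaling, the filter on all 6 arrays, array weights, the replicate block and either trend, and without vehicle replicate 3 or DNPT replicate 3. Likewise, endothelium was called without DNPT replicate 3 (adjusted p = 0.0384), principal cells without DNPT replicate 2 (0.0411) and PPAR alpha without DNPT replicate 1 (0.0482). The T, B and NK lymphocyte call held in 20 of 22 alternatives, and the intercalated cell and erythroid calls in 19 of 22. All of these calls were lost with an estimated correlation and with fry, the only alternatives with another set test. The intercalated cell and erythroid calls were also lost without the filter on dim probes. The proximal tubule list changed the direction of its set test with normexp, where its median was 0.0071 (adjusted p = 0.908, and 0.0168 to 0.908 over its alternatives), and the cause was not tested. Clock genes adjusted over the list alone numbered 5 or 6 higher and 4 or 5 lower under every alternative run for them, with each sample left out too.

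The replicate numbers did not pair the samples: deviations of same-numbered samples correlated at -0.18, -0.06 and -0.18 across genes. With a replicate block, 0 genes were higher and 0 lower, 9 lists higher and 2 lower, and the clock counts were 6 and 4. Of 115 genes followed by name, 79 kept their sign under all alternatives run for them. Signal over background limits the changes of genes that a group did not show well above background, such as Ciart, Ccdc116, Uts2b, Glt6d1 and Cd2.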

Other observations

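Several tests were chosen after the result was seen. They were tests of olfactory receptor genes and of slide and time of day for the clock genes. The same holds for DNPT replicate 1 against replicates 2 and 3 and for hepatocyte genes below the 75th percentile. It also holds for the count of hepatocyte genes taken as not induced in an acute phase response. The division of the lymphocyte list and the other genes of the next paragraph were likewise chosen afterwards.

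Within the lymphocyte list, T cell genes lay lower together. All 10 T cell genes tested, among them Cd2, Cd3d, Cd4, Cd8a and Lck, had negative changes, with a median of -0.49, and in 7 of them all DNPT values lay below all vehicle values. Cd79b (1.14), a B cell gene, had higher values in each DNPT rat with a value (there is none for replicate 2), as did Cd74 (0.60), which antigen presenting cells express. Within slide 1, all 10 T cell genes were lower in DNPT replicate 1, with a median of -0.53. None of these genes passed over all features, and whether the T cell genes and Cd79b differ in their change was not tested. Other genes varied within both groups. Slc7a13, a transporter of the late proximal tubule, was at 5.20, 2.77 and 4.78 in vehicle replicates 1 to 3 and at 3.11, 5.23 and 3.92 in DNPT replicates 1 to 3. Cyp2c11 was at 0.92, -2.28 and -0.08 and at -2.64, -0.05 and -1.63. Across genes, which are not independent replicates, deviations from the group mean correlated at 0.33 between vehicle replicate 3 and DNPT replicate 1, at 0.27 between vehicle replicate 1 and DNPT replicate 2 and at 0.26 between vehicle replicate 2 and DNPT replicate 3, and negatively in all other pairs across the groups. Deviations sum to 0 within a group, which by itself gives pairs of both signs.

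The 3 against 3 design gives 10 splits, too few for a share under 0.05. Since a split and its mirror are 1 split, another split has no higher or lower group, and its larger count of either direction was set against the real split's count in each direction. The real split called 0 genes higher and 0 lower, which all 10 splits match by construction, and the highest other count in either direction was 1. It called 9 lists higher and 2 lower, and the highest other count in either direction was 10, so that 2 splits gave as many as 9, the real one included, and 9 splits as many as 2. It had 4227 features at an unadjusted p under 0.05, with 2807 the highest other count, and 11 clock genes, with 0 the highest other count, so that for each of these 1 split of the 10, the real one, gave as many.

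Of the 15 clock genes tested, 11 passed when adjusted over the list alone. With slide as a fixed block 10 passed, but that fit sets DNPT replicate 1 alone, the only DNPT rat of slide 1, against 3 vehicle rats with a spread pooled over all samples, and 1 sample leaves slide or scan day open for the group. Of the 11 genes that passed, 10 went the way that later sampling in the light phase gives, Per1 being the exception, but the directions were set after the values were seen and for these genes alone, so this count decides nothing. Different times of day at which the groups' kidneys were taken may account for the pattern, and so may a shift of the clock by DNPT. These cannot be told apart, because the labels used here give no time for any sample and time, if it differed, would follow the groups.

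Without DNPT replicate 1, 640 features passed, 37 higher and 603 lower, and 83.3% of them were unnamed probes, against 63.6% of those tested. In DNPT replicate 1 these features showed a median of 0.050 of the change in replicates 2 and 3, so that a response which that rat lacked and an effect of slide 2 cannot be told apart: it is the only DNPT sample on slide 1. Among 39 named genes with other probes, those probes showed a median of 0.552 of the called probe's change (95% bootstrap interval 0.235 to 0.738), which leaves the hybridisation or scan of slide 2 open. Olfactory receptor genes made up 16.8% of the named genes called (18, all lower) and 2.33% of the 12622 tested (two-sided Fisher's exact test p = 4.35e-11). That test was chosen on the called genes themselves, and slide 2 holds DNPT rats only, so it decides nothing on non-specific binding, which stays open.

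Levels of Alb varied within both groups, at -4.72, 0.48 and -1.84 in vehicle replicates 1 to 3 and at -1.25, -4.74 and 3.76 in DNPT replicates 1 to 3. Of 17 tested hepatocyte genes whose levels had not been seen, 15 were higher in DNPT replicate 3 than in DNPT replicate 2, with a median difference of 1.27 (95% bootstrap interval 0.613 to 3.34), while Ambp, Serpinc1, Rbp4, Apoc3 and Fetub were higher in all DNPT than in all vehicle rats. A further list held 11 tested hepatocyte genes taken as not induced in an acute phase response, of which Alb, Ttr and Apoa1 had been seen. For these 11 genes the median was 1.90 (0.941 to 6.69). That interval reaches below the difference of 1 set beforehand. All 11 were higher, where 47.9% of all features were (two-sided exact binomial test p = 0.000302, and 0.00275 for the 8 not seen). The test was chosen afterwards and treats genes that vary together as independent, so its p-values decide nothing. The count itself covers DNPT replicates 2 and 3 only, the samples in which Alb, already seen, was lowest and highest. It decides nothing either, and an acute phase response of the kidney stays open. Traces of liver RNA may account for part of the difference between these rats but stay open, since the interval for the 17 genes also reaches below 1. Medians of 3.21 (1.27 to 6.35, 11 genes) and 2.19 (1.22 to 8.49, 9 genes) among genes below the 75th percentile in DNPT replicate 2 decide nothing, since that choice was made after the first results and on a sample of the difference tested.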
